A study of Homo sapiens with 12 samples.

How the data were processed

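The series measured RNA in 2 breast cancer cell lines, MCF-7 and T47D, by RNA sequencing of total RNA on an Illumina NovaSeq. Each line was represented by 3 control and 3 FRMD3-depleted libraries, 12 libraries in all. Per the labels, RNA was extracted with Trizol from cells grown with 10% fetal bovine serum. The titles call the treated cells FRMD3 knockouts, while the design text speaks of a knockdown. The short sample descriptions mark treated samples with "siF" and controls, which the titles call WT, with "ns", and spell out neither. How FRMD3 was depleted is therefore not stated. The wording "FRMD3-depleted" is used here for the treated samples in either case.

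The values are transcript-level FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), as deposited by the authors in a single table, per the file headers. Fragments were assigned on the hg38 build with SAMtools and featureCounts among the tools used, per the submitters' processing notes, which give no versions. The aligner and the program that turned fragments into transcript FPKM are not given in the sources used here. FPKM carries a correction for transcript length and for the total of each library, so it holds no counts, and a count model was not fitted. A search for whole fragments in the low values of the 4356 genes with 1 transcript and a known length put 39.9 to 48.1% of them within 0.1 of a whole number per library. That share is too low to recover counts for all genes. The commonest step in these values implies 10445935 to 18642485 fragments per library, with a median of 15026159. Counting error is therefore largest for genes near 1 FPKM, and the replicate spread used in each test includes it.

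The table held 83064 transcripts, which were summed to 19688 genes by Ensembl gene identifier. The 12 value columns were all used. The sums of FPKM per library ran from 311770 to 350500. FPKM is already scaled to the total of each library, so close sums do not by themselves show a common scale. Results under other scalings are therefore given below. No 2 libraries held identical values. Gene positions come from GENCODE release 29 on the same build. Because a gene's value is a sum over transcripts of different lengths, it also moves when fragments are assigned to a shorter or longer transcript of the same gene.

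Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, with FRMD3 kept whatever its level, which left 12428 genes. Values were tested as log2(FPKM + 1), so a fold change of a gene near 1 FPKM is understated. limma (version 3.58.1 in R 4.3.3) fitted the 4 group means over all 12 libraries, with moderated variances that follow a trend on mean expression. From that fit came the FRMD3-depleted minus control change in each line, the mean of both changes and the T47D change minus the MCF-7 change. Each was adjusted by the Benjamini-Hochberg method over the tested genes, with 0.05 as threshold. FRMD3 was also compared by an exact two-sided permutation test. The fold changes and adjusted p-values of genes given below come from limma.

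Replicate numbers in the titles were checked for pairing. Deviations from the group mean of the control and the FRMD3-depleted library of the same number correlated at 0.309, 0.325 and 0.286 in MCF-7 and at 0.614, 0.343 and 0.736 in T47D. Each library correlated best with its own number, so the numbers pair the libraries within each line. The fit with the replicate number of each line as a block (6 pairs) was planned as the alternative to this unblocked fit. It is given beside the unblocked value as the blocked fit wherever it changes a call or moves a count by more than 1.5 times. The labels do not say whether the replicates come from separate cultures, so the p-values measure the spread between these libraries.

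Gene lists (29, of which 28 had a tested member) were written before the data were examined and tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists within each comparison. The test was repeated with an estimated correlation. The lists were also tested with fry, which asks whether a list changed at all and not whether it changed more than other genes, so it answers another question than camera. The lists hold Notch targets and Notch components, luminal, progenitor, basal and mesenchymal markers, and junction genes. They also hold estrogen, Wnt, interferon, antigen presentation, NF-kB, p53, stress, hypoxia, cholesterol, fatty acid, immediate early, YAP and TGF-beta genes. The rest are cell cycle, histone, ribosomal, oxidative phosphorylation, mitochondrially encoded and FERM family genes, and markers of fibroblasts, endothelial cells and leukocytes. Lists can share members, so their results are not independent. CCND1, for example, is in the Notch target, Wnt target and estrogen response lists, and TFF1 in the mature luminal and estrogen response lists. The genes named below were chosen by a rule fixed at the same time. It takes FRMD3, the 8 largest rises and 8 largest falls per line among called genes whose groups do not overlap, the 5 largest each way for the mean and the difference of the lines, and up to 4 members of smallest p from each described list. It adds a fixed set of luminal, basal and Notch genes, 19 with FRMD3. Applying the same rule to the blocked fit was chosen after seeing the data.

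Alternatives covered the pseudocount, the low-value filter, the scaling between libraries, the variance model, each line fitted alone, a 1.5-fold minimum and each library left out. The design named a count test for raw counts and limma for FPKM, so limma was used. On data simulated from the MCF-7 libraries, with 200 of the 12428 genes changed, the unblocked fit recovered 38.8% of 1.5-fold, 83.6% of 2-fold and 93.9% of 3-fold changes. The blocked fit recovered 43.3%, 85.1% and 95.5%. Unchanged genes called in MCF-7 numbered 1 in the unblocked and 7 in the blocked fit. The block moved the simulated recovery little. In the measured MCF-7 libraries it moved the genes called from 14 to 1007, so the simulated shares may not carry over to them. Genes of near-identical copies, such as the HLA genes, can exchange fragments, so their single values are uncertain.

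Short sequence motifs were searched in the annotated 3' untranslated region of the most abundant transcript of each gene. Regions of at least 50 bases were available for 12244 of the tested genes. For each of 16152 motifs of 7 bases found in at least 50 genes, the ranks of the fold changes of genes with and without the motif were compared within 30 strata of region length and GC content. The resulting p was multiplied by the number of motifs (Bonferroni). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.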

Results

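Transcript levels were measured in MCF-7 and T47D, 2 estrogen receptor-positive breast cancer lines of the luminal A type, with and without depletion of FRMD3, which encodes a FERM domain protein of the band 4.1 group. The series title places the work in breast epithelial differentiation and Notch signalling. Each of the 4 groups held 3 libraries, and 15035 to 16330 genes per library had a value above 0. Libraries of one group correlated at 0.949 to 0.984 on the log2(FPKM + 1) scale, against 0.755 to 0.807 between the lines. The first principal component, which carried 79.4% of the variance, belonged to that difference between lines. Values are mean ± SD of 3 libraries (n = 3) throughout.

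FRMD3 itself (ENSG00000172159, chromosome 9, positions 83242990 to 83538546 on the minus strand of hg38) was low in both lines. In T47D it went from 1.32 ± 0.339 FPKM in control to 0.661 ± 0.145 FPKM in depleted libraries, 50.2% of control, with all 3 depleted libraries below all 3 controls. An exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 can give, and limma gave a log2 fold change of -0.47 (SE 0.15) with an adjusted p of 0.339, or 0.0737 in the blocked fit. In MCF-7 the level was 0.277 ± 0.141 FPKM in control and 0.241 ± 0.140 FPKM in depleted libraries, 87.0% of control (exact permutation p = 0.8; log2 fold change -0.04, SE 0.15, adjusted p = 0.939). Its sign was positive without MCF-7 control replicate 1 or MCF-7 depleted replicate 3 (log2 fold change 0.05 each), so no direction is given for MCF-7. The main transcript (ENST00000304195) alone averaged 0.258 FPKM in MCF-7 control and 0.191 FPKM in MCF-7 depleted libraries. In T47D it averaged 1.06 and 0.498 FPKM. The MCF-7 values of all transcripts rest on about 67 fragments in the 3 controls and 44 in the 3 depleted libraries. Those counts give a depleted-to-control ratio of 0.789 with a 95% exact binomial interval of 0.521 to 1.16, which covers counting error only. The T47D ratio was 0.482 (0.388 to 0.595) from about 274 and 131 fragments. The targeted gene therefore separates the T47D groups and does not check the labels in MCF-7, where the libraries are those labelled FRMD3-depleted.

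**Figure D1:**
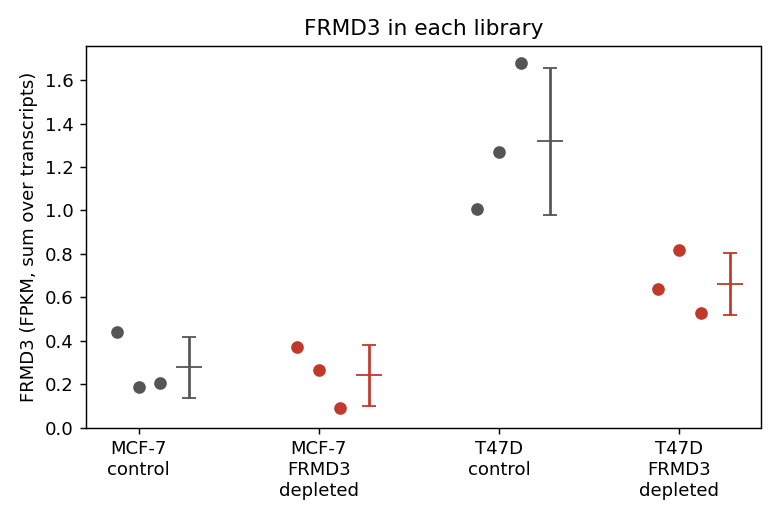
FRMD3 level in FPKM (vertical axis, linear from 0) in each of the 12 libraries, with control in grey and FRMD3-depleted in red; points are libraries and the bar beside them is the mean ± SD of 3. The T47D depleted libraries lie below the T47D controls (0.661 against 1.32 FPKM on average), while the MCF-7 groups overlap.

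The first comparison asked what changed in MCF-7. XBP1, a transcription factor of luminal cells and of the unfolded protein response, fell from 849.7 ± 61.9 to 421 ± 28.6 FPKM (log2 fold change -1.01, SE 0.12, adjusted p = 0.025). UGDH, which makes UDP-glucuronate, fell from 373 ± 40.04 to 194 ± 6.4 FPKM, and ARF1, a GTPase of Golgi transport, fell from 122 ± 1.59 to 70.8 ± 5.9 FPKM (adjusted p = 0.025 and 0.0299). FAXDC2, TPRG1L, ZNF148 and GPD1L also fell, with log2 fold changes of -1.24, -0.89, -0.84 and -0.79. UGDH, ARF1, ZNF148 and GPD1L carry the 3' UTR motif given among the other observations, and XBP1, FAXDC2 and TPRG1L do not. SELL, the leukocyte adhesion receptor L-selectin, rose from 4.16 ± 0.983 to 11.7 ± 1.4 FPKM, and ST8SIA4, a polysialyltransferase, rose from 5.57 ± 0.459 to 14.3 ± 1.33 FPKM (adjusted p = 0.0321 and 0.00162). STX12, MAP7D1, ZNF548, IFT27 and ATXN7L3B rose by 0.86, 0.75, 0.69, 0.68 and 0.64 on the log2 scale. These 14 genes, 7 higher and 7 lower, were all that passed of 12428, with 1747 at an unadjusted p under 0.05. Of the genes called, 50% were higher as deposited, 58.3% after rescaling to equal totals, 25% with median-of-ratios scaling and 31.3% with quantile normalisation. The groups did not overlap for 24.0% of genes, against 10% expected if the libraries of the line were exchangeable. Paired libraries are not, so the 10% is no strict reference.

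With the replicate pairs as a block, 1007 genes passed in MCF-7, 727 higher and 280 lower. Among called genes whose groups do not overlap, the largest rises belonged to immune genes. CD74, the invariant chain of MHC class II, rose from 1.46 ± 1.04 to 12.5 ± 5.71 FPKM (log2 fold change 2.46, blocked adjusted p = 0.00116), and HLA-DRA from 0.834 ± 0.495 to 7.75 ± 4.48 FPKM. The interferon-induced RARRES3, XAF1, IFIT2, PSMB9, IFI44 and MX2 rose by 2.36, 2.32, 2.23, 2.13, 2.07 and 2.01. RAB31 (47.9 ± 4.4 to 19.2 ± 3.98 FPKM), CALML5 (43.2 ± 16.1 to 20.2 ± 8.76 FPKM), ABHD2 (36.3 ± 6.02 to 17.5 ± 2.97 FPKM) and SYTL5 (58.6 ± 5.92 to 29.6 ± 8.37 FPKM) were among the largest falls of such genes, with FAXDC2, XBP1, NPIPA5 and C2orf76. RAB31, ABHD2 and SYTL5 also carry the 3' UTR motif, and CALML5, FAXDC2, XBP1 and C2orf76 do not. The share of higher genes depends on scaling: it was 72.2% as deposited, 78.3% after rescaling to equal totals, 52.2% after median-of-ratios scaling and 48.9% after quantile normalisation. Rescaling to equal totals moved the median of all MCF-7 genes to 0.11 on the log2 scale, from 0.07 as deposited.

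Interferon response genes stood higher in depleted MCF-7 libraries: all 43 measured members had a positive change, with a median of 1.11 (camera adjusted p = 1.43e-10; adjusted p = 0.78 with an estimated correlation). In the unblocked limma fit 0 passed on their own, over all genes or adjusted over the list alone (20 at an unadjusted p under 0.05), and 28 passed in the blocked fit (39 adjusted over the list alone). IRF1, a transcription factor of this response, went from 10.2 ± 3.72 to 19.98 ± 5.33 FPKM (blocked adjusted p = 0.00571). All 19 antigen presentation genes were also higher, by a median of 1.28 (adjusted p = 1.87e-09; adjusted p = 0.756 with an estimated correlation). Over the list alone 15 of them passed in the unblocked fit, and all 19 passed in the blocked fit, over all genes and adjusted over the list alone. HLA-B went from 31.9 ± 19.2 to 111 ± 44.8 FPKM and HLA-C from 72.95 ± 30.5 to 169.7 ± 80.4 FPKM, as near-identical genes with uncertain single values. Levels of these genes varied widely within the control group: IFIT3 ran from 6.23 to 67.5 FPKM over the 3 MCF-7 controls. NF-kB and TNF response genes were higher for all 21 members (median 0.44, adjusted p = 0.0206; adjusted p = 0.78 with an estimated correlation). TNFAIP2 and NFKB2 were among the 10 that passed in the blocked fit (13 adjusted over the list alone).

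Estrogen response genes fell in MCF-7: 30 of 34 measured members had a negative change, with a median of -0.34 (adjusted p = 6.29e-12), and the call held with an estimated correlation (adjusted p = 0.0302). In the unblocked limma fit 0 members passed over all genes (9 at an unadjusted p under 0.05) and 3 adjusted over the list alone, against 13 and 20 in the blocked fit. CCND1, which encodes cyclin D1, went from 415 ± 33.3 to 216 ± 22.1 FPKM (blocked adjusted p = 0.00907). The secreted factor TFF1 went from 1712 ± 418 to 1005 ± 328 FPKM, the progesterone receptor gene PGR from 12.3 ± 2.79 to 7.99 ± 1.62 FPKM and MYB from 28.5 ± 7.42 to 16.6 ± 4.06 FPKM (blocked adjusted p = 0.0181, 0.0135 and 0.0167). The estrogen receptor gene ESR1 itself stood at 56.9 ± 10.2 FPKM in control and 28.2 ± 7.58 FPKM in depleted libraries and did not pass (adjusted p = 0.128, blocked 0.0706).

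Mature luminal markers were lower in MCF-7, with 19 of 25 members negative and a median of -0.31 (adjusted p = 5.1e-08; adjusted p = 0.135 with an estimated correlation). XBP1 passed in the unblocked fit (2 lower adjusted over the list alone), and 11 were lower in the blocked fit (15 lower and 1 higher adjusted over the list alone). SPDEF, a luminal transcription factor, went from 45.1 ± 7.95 to 27.1 ± 3.11 FPKM and the keratin gene KRT8 from 3777 ± 664 to 2490.4 ± 940.2 FPKM (blocked adjusted p = 0.01 and 0.0493). GATA3 (116 to 157 FPKM), FOXA1 (101 to 87.7 FPKM), KRT18 (2799.6 to 2257 FPKM) and CDH1 (193 to 166 FPKM) did not pass in either fit. Luminal progenitor markers passed only with the block (blocked adjusted p = 0.0222; adjusted p = 0.462 with an estimated correlation), with LCN2, SLPI, CYP24A1 and EHF higher among 8 measured. Basal markers (17 measured) and mesenchymal genes (8 measured) showed no shift as lists (adjusted p = 0.564 and 0.763). VIM stood at 3.59 ± 2.07 to 4.47 ± 2.84 FPKM, and KRT5, KRT14 and NOTCH4 were below the level tested.

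Notch target genes showed no call in MCF-7 (15 measured, 8 negative, median -0.09, adjusted p = 0.125; it was 0.0264 without MCF-7 depleted replicate 1 and 0.0325 without MCF-7 control replicate 2). HES1 (37.5 to 35 FPKM), HEY1 (0.509 to 0.787 FPKM) and NRARP (13.4 to 11.6 FPKM), 3 direct targets, did not pass. In the blocked fit HEY2 fell from 7.04 ± 1.31 to 3.31 ± 0.561 FPKM together with CCND1, and SOX9 rose from 4.04 ± 1.59 to 7.51 ± 4.44 FPKM. Notch receptors, ligands and processing genes did not shift as a list (31 measured, adjusted p = 0.763). Of these, MAML2, a coactivator, and NCSTN, a subunit of gamma-secretase, were higher in the blocked fit (0.497 ± 0.146 to 1.24 ± 0.101 FPKM and 12.5 ± 1.69 to 19.6 ± 5.18 FPKM). The receptors NOTCH1, NOTCH2 and NOTCH3 and the ligand JAG1 had log2 fold changes of 0.18, -0.09, 0.08 and -0.16, none of which passed.

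Growth-related lists were lower in MCF-7. S and M phase cell cycle genes had 50 of 55 members negative (median -0.21, adjusted p = 5.86e-07; adjusted p = 0.78 with an estimated correlation), with 0 passing in the unblocked limma fit (2 at an unadjusted p under 0.05) and 8 in the blocked fit (10 adjusted over the list alone). The replication licensing gene MCM7 went from 133 ± 8.65 to 97.9 ± 8.31 FPKM and TK1, the S phase thymidine kinase, from 48.99 ± 9.999 to 35.7 ± 7.51 FPKM (blocked adjusted p = 0.0279 and 0.02). All 12 measured replication-dependent histone genes were negative (median -0.45, adjusted p = 3.15e-05; adjusted p = 0.756 with an estimated correlation). Cytosolic ribosomal protein genes had 67 of 73 members negative by a median of -0.22 (adjusted p = 8.69e-18; adjusted p = 0.371 with an estimated correlation), and 0 passed singly by limma in either fit (14 at an unadjusted p under 0.05 without the block). With quantile normalisation the ribosomal median was -0.08 in MCF-7, and in T47D it was 0.05 against -0.05 as deposited. Smaller shifts past the threshold were seen for nuclear-encoded oxidative phosphorylation genes (median -0.07, adjusted p = 0.00799) and for hypoxia and glycolysis genes (median -0.05, adjusted p = 0.0313); with an estimated correlation both had an adjusted p of 0.78. The oxidative phosphorylation median was negative in 1 of 3 MCF-7 pairs, the adjusted p was 0.527 without depleted replicate 1, where the direction reversed, and 0.0564 without control replicate 2. Over the scalings the MCF-7 median ran from -0.04 (equal totals) to -0.14 (median of ratios) for oxidative phosphorylation genes and from -0.02 to -0.12 for hypoxia and glycolysis genes. Wnt target genes passed only with the block (blocked adjusted p = 0.0372, against 0.112; adjusted p = 0.299 with the block and an estimated correlation).

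No other list passed in MCF-7. The adjusted p was 0.763 for junction genes, 0.976 for p53 targets, 0.782 for unfolded protein response genes, 0.763 for cholesterol synthesis and 0.362 for fatty acid synthesis. It was 0.344 for immediate early genes, 0.483 for YAP targets, 0.813 for TGF-beta genes, 0.763 for the FERM family and 0.189 for mitochondrially encoded genes. Markers of fibroblasts (7 measured) and leukocytes (2 measured) gave 0.483 and 0.813, and endothelial markers were all below the level tested. Without the MCF-7 replicate 1 pair, whose depleted library has the fewest implied fragments (10445935), 1 gene passed in MCF-7 and 331 in the blocked fit. Leaving out 1 library left 1 gene without MCF-7 control 3, MCF-7 depleted 1, T47D control 2 or T47D depleted 2, and 2 to 9 without any of the others apart from T47D control 3 and T47D depleted 1.

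In T47D the lists of smallest p by camera were cell cycle and estrogen response genes, both lower, and interferon response genes, which were higher. With an estimated correlation none of the 3 passed (adjusted p = 0.655, 0.0759 and 0.655 with an estimated correlation). No gene passed in the unblocked limma fit (0 of 12428, with 1163 at an unadjusted p under 0.05). The groups did not overlap for 13.6% of genes, against 10% expected of exchangeable libraries, which these paired libraries are not. With the pairs as a block 537 genes passed, 239 higher and 298 lower. STC1, a secreted glycoprotein, fell from 27.4 ± 13.6 to 10.7 ± 4.82 FPKM, AR, the androgen receptor gene, from 7.6 ± 0.136 to 3.56 ± 1.4 FPKM and STMN1, a microtubule-destabilising protein, from 131 ± 35.2 to 65.4 ± 13.1 FPKM (blocked adjusted p = 0.00736, 0.0325 and 0.0205). NKAIN1, TFF1, HOXC5, TPBG and ABAT fell by 1.12, 0.97, 0.97, 0.96 and 0.88 on the log2 scale. The chemokine gene CCL20 rose from 6.52 ± 3.47 to 14.5 ± 6.63 FPKM, LEPROT from 6.19 ± 0.314 to 16.7 ± 1.78 FPKM and SYNE1 from 1.28 ± 0.638 to 4.19 ± 0.806 FPKM, with PGLYRP4, TNFSF15, PATL2, PLEKHG4 and OGFR also among the largest rises of called genes whose groups do not overlap. Leaving out the T47D replicate 3 pair, whose libraries deviate together most strongly (0.736), left 17 genes in the blocked fit.

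Estrogen response genes in T47D had 31 of 34 members negative with a median of -0.40 (adjusted p = 7.26e-09; adjusted p = 0.0759 with an estimated correlation, or 0.0217 with the block as well). In the unblocked limma fit 0 passed over all genes (10 at an unadjusted p under 0.05) and 2 adjusted over the list alone, against 11 and 22 in the blocked fit. PGR went from 101 ± 50.8 to 58.3 ± 33.3 FPKM, CCND1 from 108 ± 38.3 to 51.4 ± 21.4 FPKM and STC2, a secreted glycoprotein, from 108 ± 63.2 to 62.9 ± 37.7 FPKM (blocked adjusted p = 0.01, 0.01 and 0.0244). ESR1 stood at 21.4 ± 2.82 to 24.9 ± 6.99 FPKM and did not pass. Mature luminal markers were lower for 19 of 25 members (median -0.31, adjusted p = 0.000635; adjusted p = 0.389 with an estimated correlation), with 6 passing in the blocked fit (8 adjusted over the list alone). The list's median was -0.16 with quantile normalisation, and -0.16 as deposited for the 20 members without the 3' UTR motif given among the other observations. Of the 6, SCUBE2 went from 23.2 ± 11.7 to 13.1 ± 7.14 FPKM and the prolactin receptor gene PRLR from 347 ± 101 to 248 ± 71.9 FPKM (blocked adjusted p = 0.01 and 0.0244). SCUBE2 and PRLR carry that motif, as do PGR and STC2 above. CCND1 does not, nor do TFF1, AR and MYB, which are also among the 6. GATA3 (102 to 93.9 FPKM), FOXA1 (69.96 to 65.98 FPKM), KRT8 (1099 to 1157 FPKM), KRT18 (915 to 791 FPKM), CDH1 (128 to 126 FPKM) and VIM (5.16 to 5.42 FPKM) did not pass.

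Notch target genes were lower in T47D, with 10 of 15 members negative and a median of -0.21 (adjusted p = 0.00281; adjusted p = 0.389 with an estimated correlation). CCND1, also a member of the estrogen response and Wnt target lists, and HEY2 (2.19 ± 1.06 to 1.07 ± 0.678 FPKM) passed in the blocked fit. Adjusted over the list alone, 3 members passed in the unblocked fit and 5 in the blocked fit. MYC stood at 15.8 to 6.66 FPKM and IGF1R, the insulin-like growth factor receptor gene, at 18.3 to 11.7 FPKM (blocked adjusted p = 0.107 and 0.0987). The direct targets HES1 (21.99 to 23.5 FPKM), HEY1 (0.945 to 0.956 FPKM) and NRARP (12.8 to 10.3 FPKM) did not pass. Notch components had an adjusted p of 0.793, with NCSTN higher in the blocked fit (28.97 ± 1.3 to 42.8 ± 4.95 FPKM) and NOTCH1, NOTCH2, NOTCH3 and JAG1 at log2 fold changes of -0.05, -0.11, -0.21 and 0.04, none of which passed.

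Interferon response genes in T47D had 42 of 43 members positive with a median of 0.71 (adjusted p = 9.08e-08; adjusted p = 0.655 with an estimated correlation), and 6 passed in the blocked fit (18 adjusted over the list alone). Without T47D control replicate 1 the list's adjusted p was 0.127. OASL went from 49.3 ± 51.4 to 124 ± 83.6 FPKM and SAMD9L from 9.73 ± 8.01 to 18.6 ± 8.2 FPKM (blocked adjusted p = 0.0323 and 0.0325). The 3 T47D controls ranged from 29.5 to 645 FPKM for IFIT3. All 19 antigen presentation genes were positive (median 0.68, adjusted p = 6.4e-05; adjusted p = 0.655 with an estimated correlation), with 8 passing in the blocked fit (13 adjusted over the list alone), CD74 among them (181 ± 155 to 384 ± 314 FPKM). Unfolded protein and integrated stress response genes were higher (24 of 32 positive, median 0.18, adjusted p = 0.00422; adjusted p = 0.655 with an estimated correlation), with DDIT3 going from 62.9 ± 56.4 to 118 ± 83.2 FPKM (blocked adjusted p = 0.0143). NF-kB genes passed with the block (adjusted p = 0.0908 against a blocked 0.000119; adjusted p = 0.275 with the block and an estimated correlation).

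Cell cycle genes in T47D had 54 of 55 members negative (median -0.37, adjusted p = 7.26e-09; adjusted p = 0.655 with an estimated correlation), and 15 passed in the blocked fit (47 adjusted over the list alone). BUB1B, a spindle checkpoint kinase, went from 20.1 ± 7.36 to 13.6 ± 4.67 FPKM and TK1 from 58.8 ± 22.1 to 41.1 ± 18.8 FPKM (blocked adjusted p = 0.0244 and 0.0199). Histone genes were negative for all 12 (median -0.42, adjusted p = 0.000169; adjusted p = 0.655 with an estimated correlation). Fatty acid synthesis genes were lower (14 of 21 negative, adjusted p = 0.0298, blocked 0.0609; adjusted p = 0.389 with an estimated correlation), and SCD, ACLY and ELOVL5 fell in the blocked fit by 0.50, 0.36 and 0.38 on the log2 scale. The remaining lists did not pass in T47D: junction genes, p53 targets and TGF-beta genes had adjusted p of 0.198, 0.202 and 0.203, and ribosomal protein and immediate early genes 0.0845 and 0.0845. Wnt targets gave 0.151, luminal progenitor markers 0.857, basal markers 0.885, mesenchymal genes 0.623, hypoxia genes 0.554 and cholesterol synthesis 0.554. YAP targets gave 0.537, the FERM family 0.995, oxidative phosphorylation 0.554, mitochondrially encoded genes 0.348, fibroblast markers 0.795 and leukocyte markers 0.343.

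Which changes were shared by the lines was the next comparison. In the mean of both lines, the largest falls among genes called in the unblocked fit were those of TFF1, CCND1, RAB31, GSN, which encodes gelsolin, and TPRG1L. Their log2 fold changes were -0.88, -1.004, -0.95, -0.89 and -0.84 (limma adjusted p from 0.00597 to 0.0458). Among the same called genes PATL2, SYNE1, OGFR, LEPROT and TRIM38 had the largest rises, from 0.90 to 1.03. Of 12428 genes 210 passed, 132 higher and 78 lower, and 2317 passed in the blocked fit, 1417 higher and 900 lower. Leaving out 1 library moved the 210 by more than 1.5 times for each of the 12, from 16 (without T47D depleted replicate 2) to 663 (without T47D control replicate 3). The blocked fit added IFIT2, RARRES3, CD74, IFIT3 and HLA-DRA as the largest rises, with AC068580.4 as the largest fall. As deposited 62.9% of the genes called in the unblocked fit were higher, against 76.6% after rescaling to equal totals, 40.7% with median-of-ratios scaling and 36.5% with quantile normalisation. For the blocked fit those shares were 61.2%, 71.2%, 50.04% and 45.01%.

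Across genes the changes in the lines correlated with a Pearson r of 0.438, and 67.4% of genes had the same sign; genes are not independent replicates, and the lines share no control libraries. No gene passed in both lines in the unblocked fit. In the blocked fit 127 genes were higher in both lines, where independent lists would share 13.98, and 105 were lower in both, where independent lists would share 6.71. Together these 232 became 8 without the T47D replicate 3 pair and 117 without the MCF-7 replicate 1 pair. On the 537 genes called in T47D, the MCF-7 pairs moved in the T47D direction for 85.3%, 88.1% and 89.4% of genes. A swap of the control and depleted library within an MCF-7 pair would reverse that direction, so these shares argue against one. They do not show that FRMD3 fell in MCF-7. By list, interferon, antigen presentation, NF-kB and unfolded protein response medians were positive in 6 of 6 pairs. Estrogen response, mature luminal, Wnt target, cell cycle and histone medians were negative in 6 of 6 (exact sign-flip permutation p = 0.0312 each, the smallest 6 pairs can give, and 0.0972 after adjustment over the lists). The sign-flip test was chosen after seeing the data, and some of these lists share members, so they are not separate results. For the mean of both lines the estrogen response list kept its call with an estimated correlation (adjusted p = 0.0215).

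**Figure D2:**
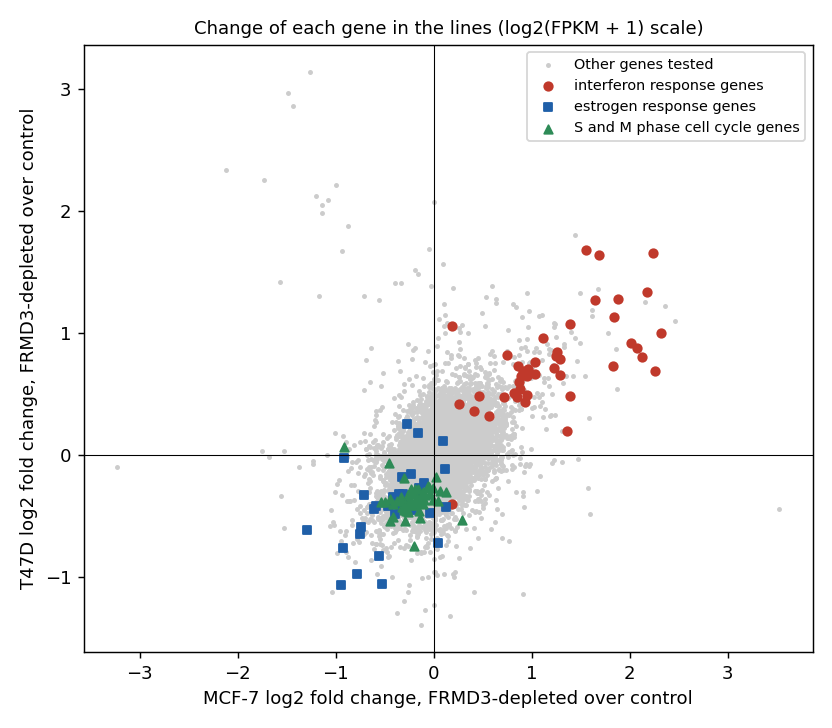
Log2 fold change of FRMD3-depleted over control, on the log2(FPKM + 1) scale, in MCF-7 (horizontal axis) and T47D (vertical axis) for each of the 12428 genes tested; colours mark the 43 interferon response, 34 estrogen response and 55 cell cycle genes. Interferon genes lie to the upper right (medians 1.11 and 0.71), and estrogen response genes mostly to the lower left (medians -0.34 and -0.40).

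**Figure D3:**
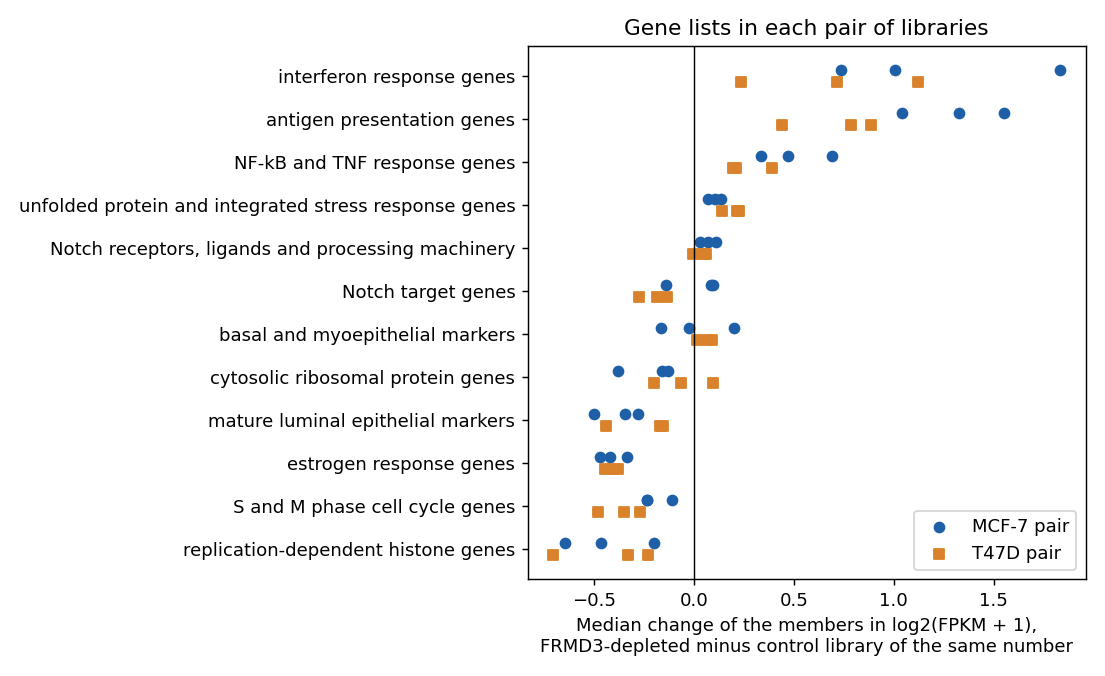
Median log2 change of each gene list in each pair of libraries of the same replicate number (FRMD3-depleted minus control, horizontal axis), with MCF-7 pairs as blue circles and T47D pairs as orange squares. Interferon response medians run from 0.24 to 1.83 and estrogen response medians from -0.47 to -0.33.

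The last comparison tested whether the change differed between the lines. ST8SIA4 (chromosome 5, positions 100806935 to 100903266) was the 1 gene that passed: it rose in MCF-7 as given above and stood at 0.0387 and 0.00772 FPKM in T47D control and depleted libraries, a difference of -1.27 on the log2 scale (SE 0.15, adjusted p = 0.0377). In the blocked fit 0 genes passed (1383 at an unadjusted p under 0.05), and ST8SIA4 had an adjusted p of 0.0859. ESR1 had a difference of 1.19 that did not pass (adjusted p = 0.999). Among lists, ribosomal protein genes (0.18 median difference), unfolded protein response genes (0.15) and antigen presentation genes (-0.67) differed between lines, with adjusted p of 4.69e-12, 0.00103 and 0.0275. With an estimated correlation each had an adjusted p of 0.937. The interferon, NF-kB and cell cycle lists passed for the difference only with the block (blocked adjusted p = 0.0135, 0.0135 and 0.00768; each 0.819 as adjusted p with the block and an estimated correlation), and the Notch target list did not (adjusted p = 0.472).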

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

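Of the tests below, those of a single pair carrying the interferon rise and of a response to a transfected duplex were chosen after the results were seen. A difference between the lines under the same contrast picked out 4 results. ST8SIA4 differed by -1.27 on the log2 scale, rising in MCF-7 and near 0 FPKM in both T47D groups. Cytosolic ribosomal protein genes (adjusted p = 4.69e-12), unfolded protein and integrated stress response genes (adjusted p = 0.00103) and antigen presentation genes (adjusted p = 0.0275) differed as lists, none of them with an estimated correlation (adjusted p = 0.937 each). Groups of 3 are too small for a search for outlying libraries.

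Other splits of the libraries were counted for each number of called genes. In MCF-7 the real split gave 14 genes and the highest of the others 3, 1 of 10 splits giving as many; 10 splits are too few for a share under 0.05, in T47D as well. In T47D all 10 splits gave at least the real 0, and the highest other gave 813. That split parts only 1 of the 3 pairs and places both replicate 3 libraries together, which points to a structure of the T47D samples by replicate number. Among 100 splits drawn for the mean of both lines, 2 gave at least the real 210 genes, a share under 0.05. Most of those splits ignore the pairs, so this share does not exclude chance for paired libraries. The highest other, 1300 genes, parts 4 of the 6 pairs. Of the 100, 14 part all 6 pairs, too few for a share under 0.05, and the highest other among them is 2. With the block, 1 of 32 sign flips of the pairs gave the real 2317 genes and the highest other gave 0, which argues against chance for that count. That share is the smallest that 32 flips can give. Within 1 line the block allows only 4 flips, too few for a share under 0.05. There the highest other gave 0 genes in MCF-7 and 1 in T47D, against the real 1007 and 537. For the difference between the lines 36 of 100 splits gave at least 1 gene, so chance cannot be excluded there (highest other 1300, again many times the real count).

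The rise of interferon response genes is the first pattern weighed. It was not carried by 1 pair, since the smallest median over the 6 pairs was 0.24 on the log2 scale. Leukocytes mixed into the cultures are argued against by PTPRC, which every leukocyte expresses, at no more than 0.0356 FPKM in any library, with LYZ at no more than 0.139 FPKM; only CORO1A (up to 14.2) and LCP1 (up to 6.81) of the 16 markers were high enough to test. If FRMD3 was depleted with a transfected duplex, which the labels do not say, a response to that duplex and not to the loss of FRMD3 may be the source. The list's median was 0.71 in T47D, where the FRMD3 ratio to control was 50.2% by FPKM and 0.482 by fragments. It was 1.11 in MCF-7, where that ratio was 87.0% by FPKM and 0.789 by about 67 and 44 fragments. The median difference was -0.37. Its camera adjusted p was 0.254, or 0.0135 in the blocked fit. With an estimated correlation these became 0.937 and 0.819. The intervals of the FRMD3 ratio (0.388 to 0.595 in T47D and 0.521 to 1.16 in MCF-7) cover counting error only and leave out the spread between libraries. Their overlap is no test of a difference, so the lines were not ranked by depletion. With 1 contrast per line a response to a duplex cannot be told apart from an effect of FRMD3.

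The fall of estrogen response genes is the second. A gene length or GC content trend between libraries is argued against: after removal of that trend in the blocked fit the list's median was -0.44 in MCF-7 (-0.34 before) and -0.40 in T47D (-0.40 before), and the larger adjusted p of the lines was 9.47e-14. Direct silencing of its members through the 3' UTR motif described among the other observations does not account for the whole list either, since the 29 members without that motif had a median of -0.34 in the mean of both lines, 26 of them negative; the 5 members with it had a median of -0.70, all 5 negative, so a part in their fall stays open. ESR1 carries 1 copy of the motif and had log2 fold changes of -1.01 in MCF-7 and 0.18 in T47D, neither of which passed. Whether ESR1 contributes in MCF-7 is untested. For the list, an effect of FRMD3 stays open beside sites that match the motif in part and an indirect effect of other silenced genes. If a duplex was transfected, a response to it stays open as well.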

How the results depend on the processing

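Estrogen response genes kept their direction in both lines under every setting run, and kept their call except with an estimated correlation in T47D. Calls of single genes in one line were few without the replicate block, and most counts below move; why they move was not tested. The unblocked fit gave 14 genes in MCF-7, 0 in T47D, 1 with a different change in the lines, 210 for the mean and 0 called the same way in both lines. The replicate block gave 1007, 537, 0, 2317 and 232 in that order. For the mean of both lines it added calls of the Wnt target list (adjusted p = 0.0696 to a blocked 0.0437; adjusted p = 0.308 with the block and an estimated correlation) and the unfolded protein response list (0.175 to a blocked 0.0134; adjusted p = 0.320 with the block and an estimated correlation). The gene with a different change was lost (0) at pseudocounts of 0.1 and 0.5, with a 5 FPKM filter, after rescaling to equal totals and with quantile normalisation, which gave 2 genes in T47D. Without the filter, counts were 47 in MCF-7, 15 in T47D, 6 different and 2 shared. MCF-7 fitted alone gave 0. Requiring 1.5-fold left 48 genes for the mean.

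The next 3 sentences give settings chosen after seeing the data. Without the MCF-7 replicate 1 pair 1 gene was called in MCF-7, 1 in T47D, 0 different and 11 for the mean (with the block 331, 701, 0, 1895 and 117 shared). Without the T47D replicate 3 pair the counts were 60 in MCF-7, 1 in T47D and 486 for the mean (with the block 512, 17, 1376 and 8 shared). With the block and a length and GC trend removed they were 1249, 857, 2610 and 391 shared. Leaving out 1 library, as planned, gave 1 (without MCF-7 control 3) to 15 genes in MCF-7, 0 to 3 in T47D, 0 to 1 different and 16 (without T47D depleted 2) to 663 (without T47D control 3) for the mean, which each of the 12 libraries moved by over 1.5 times; the correlation of the lines ran from 0.293 (without T47D control 1) to 0.491; where this leaves a group of 2, the spread is shared with the other groups. For Notch targets in MCF-7 the adjusted p ran from 0.0264 (without MCF-7 depleted 1; 0.0325 without MCF-7 control 2) to 0.487, and for interferon genes in T47D from 7.92e-17 to 0.127 (without T47D control 1).

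With an estimated correlation the adjusted p in MCF-7 was 0.135 for mature luminal markers, 0.780 for cell cycle and 0.780 for interferon genes; in T47D it was 0.389 for Notch targets, 0.389 for mature luminal markers, 0.0759 for estrogen response, 0.655 for cell cycle and 0.655 for interferon genes. fry, which tests a list against no change and not against other genes, gave 0.113, 0.778 and 0.316 in MCF-7, and 0.296, 0.296, 0.600 and 0.600 in T47D for the same lists without estrogen response. The block with an estimated correlation, chosen after seeing the data, gave 0.0991, 0.299 and 0.414 in MCF-7, and 0.397, 0.219, 0.219 and 0.451 in T47D. Oxidative phosphorylation genes in MCF-7 turned from lower to higher, without a call, when the replicate 1 pair was left out (adjusted p = 0.831, with the block 0.888) and without MCF-7 depleted replicate 1 (0.527, the highest with 1 library left out, against a lowest of 2.43e-05 without MCF-7 depleted 2). Dropping the variance trend gave 15 genes in MCF-7 and 214 for the mean, and the robust variance 215 for the mean; neither changed a direction or a call of a list or of FRMD3. The planned quasi-likelihood and negative binomial tests (edgeR with TMM, edgeR without the low-count filter, and DESeq2) were not run, since no whole reads could be recovered from FPKM. Over all settings, the other single-gene tests kept their side of the threshold in 14473 cases, passed newly in 636, no longer passed in 157 and changed sign after a call in the unblocked fit in 0. List tests did so in 1325, 39, 57 and 3. Those 3 fall in the settings above where oxidative phosphorylation genes turned without a call. Among those that kept their side, the sign turned without a call in 304 gene and 91 list cases. FRMD3 in MCF-7 also turned, from -0.04 to 0.05 without MCF-7 control 1 (0.0472) or MCF-7 depleted 3 (0.0475), without a call.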

Other observations

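The motif search itself was planned before its result was seen; the per-pair, per-region and flanking-base tests of the top motif, the search for genes that move 10-fold within a group and the zinc finger count were chosen after. The control libraries of the lines differ widely: 7509 of 12428 genes differed, 3854 higher and 3655 lower in T47D. TFF1 stood at 1712 ± 418 FPKM in MCF-7 and 6.54 ± 0.587 FPKM in T47D, and UGDH at 373 and 6.67 FPKM. ESR1 was higher in MCF-7 (56.9 against 21.4 FPKM), while PGR (12.3 against 101 FPKM), PRLR (21.6 against 347) and AR (2.38 against 7.6) were higher in T47D. The immune genes MX1, CD74 and HLA-B were higher in T47D: MX1 stood at 3.2 against 686 FPKM, CD74 at 1.46 against 181 and HLA-B at 31.9 against 841 (adjusted p = 7.9e-08, 1.4e-05 and 4.46e-05 by limma). FRMD3 itself was higher in T47D (0.277 against 1.32 FPKM, adjusted p = 0.000401).

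Genes lower in both lines form the third pattern weighed. Off-target silencing through a shared short seed, the way a small interfering RNA can act like a microRNA, predicts a short 3' UTR motif that goes with lower values in both lines and occurs in the FRMD3 transcript. Of 16152 motifs 4 passed in both lines for lower values and 0 for higher values, and the 4 overlap in sequence. Of the 4, 3 occur in the main FRMD3 transcript and TGAATCC does not. GAATCCA ranked first in both lines, with z = -12.3 in MCF-7 (Bonferroni p = 4.83e-31, n = 12244 genes, which are not independent replicates) and z = -11.0 in T47D (Bonferroni p = 2.84e-24, n = 12244). It ranked first in each of the 6 pairs taken alone (z from -8.46 to -11.0). It lies in the 3' UTR of 76 of the 271 searched genes called lower in the blocked fit in MCF-7 and of 73 of 292 in T47D, against 8.74% and 8.64% of genes not called and 5.15% and 5.04% of genes called higher. These values go with off-target silencing through a shared short seed for part of the genes that fell. Most genes called lower carry no copy of GAATCCA in the region searched. Sites that match it only in part were not counted, so direct silencing is not excluded for these genes. Their fall also stays open between FRMD3, indirect effects and, if a duplex was transfected, a response to it.

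Among named genes that fell in both lines in the blocked fit, ABAT, ABHD2, ARF1, GPD1L, PGR, PRLR, RAB31, RRM2B, SCD, SCUBE2 and STC2 carry the motif, ABHD2 at 3 positions and PGR at 2. CCND1, TFF1, GSN, HEY2, MYB and STMN1 are among those that do not. Of the named genes that passed as lower in the blocked fit in MCF-7 only, CAV1, SYTL5, UGDH and ZNF148 carry the motif. XBP1, FAXDC2, RET and SPDEF are among those that do not. Genes with 0, 1 and at least 2 copies had median log2 fold changes of 0.08, 0.01 and 0.00 in MCF-7 and of 0.01, -0.06 and -0.08 in T47D. Genes with the motif in the coding region and not in the 3' UTR (1422) had medians of 0.06 and -0.01. By the base after the motif, medians ran from -0.03 (A, 238 genes) to 0.03 (C, 168) in MCF-7 and from -0.06 (G, 329) to -0.04 (C) in T47D. By the base before it they ran from -0.03 (C, 30 genes) to 0.01 (A, 376) and from -0.07 (G, 224) to -0.01 (C); these differences were not tested. Between the control libraries of the lines the motif had z = -1.46 and ranked 2100. In the main FRMD3 transcript (ENST00000304195) it occurs once, at position 962, in the coding part of exon 8 of 14 (chromosome 9, positions 83311899 to 83311905 of hg38, minus strand); 25.1% of all motifs searched occur somewhere in this transcript of 5297 bases. No sequence of a silencing reagent was used here, so whether a seed pairs with this motif was not tested.

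In 65 of the 12428 genes (0.523%), the highest library of a group with at least 10 FPKM was at least 10 times the lowest. CLDN4 ran from 0.281 to 100.5 FPKM in T47D controls and from 0.9 to 139 FPKM in depleted MCF-7 libraries, and was under 1 FPKM in 4 of 12 libraries. MT-CYB, MT-ND5 and MT-ND6 did so in 3 of the 4 groups. The interferon genes IFI44, IFIT2, IFIT3, MX2, OASL and XAF1 are also among the 65, in the control group of 1 or both lines.

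Zinc finger genes with a ZNF symbol (454 tested) had a median log2 fold change of 0.10 in the mean of both lines, against 0.04 for all genes (camera p = 0.000381; p = 0.162 with an estimated correlation). After removal of the length and GC trend the medians were 0.05 and -0.00399.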
